A study of Homo sapiens with 8 samples.

How the data were processed

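The deposited files of 8 libraries were used, each with RSEM expected counts, FPKM and effective lengths per gene. Per the submitters' processing notes, reads were aligned with Bowtie2 to GRCh38 and quantified with RSEM. The expected counts were made by RSEM per the submitters' processing notes, and so were the FPKM values. The effective lengths were taken as deposited. The versions of Bowtie2 and RSEM, the annotation release, the strand setting, the library kit and the sequence and number of the hairpins are not given in the sources used here. Total RNA had been prepared with a mini-prep kit and DNase digestion, per the labels.

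The library files held 60666 genes, 60437 with a symbol, and the series matrices held the values of the library files. Of the positive expected counts, 30.6% were not whole numbers, and they were rounded before testing. Gene types, coordinates, exons and 3′ UTRs came from GENCODE 29, which held 58420 of the identifiers. Libraries showed 22345 to 23920 genes with a count, 97.4% to 98.3% of counts in protein-coding genes and 2.55% to 3.44% in mitochondrial genes. A floor of 3 counts per library, equal to 0.143 to 0.178 CPM, was used for detection, and floors cover counting error only. Where a group was at 0 in both libraries the fold is a lower bound against that floor. The replicates of a group differed by 2.23 to 7.11 times the counting variance, the largest value being that of the PC3 control, and log2 CPM correlated at 0.9979 to 0.9983.

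Differential expression was tested with edgeR's quasi-likelihood F test on 17776 genes that passed filterByExpr (minimum count 10, minimum total 15), after TMM scaling (factors 0.926 to 1.074). The 8 libraries were fitted together with 4 group means, leaving 4 residual degrees of freedom. The common dispersion was 0.00278, a biological coefficient of variation of 5.3%. The contrasts were the knockdown in each line, the difference of the PC3 effect less the BPH1 effect, and the PC3 control less the BPH1 control. P-values were adjusted by Benjamini-Hochberg over all genes tested, at 0.05. Log2 CPM values used a prior count of 2.

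The 40 gene lists, with 686 members of which 653 were tested, were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists by Benjamini-Hochberg, and the estimated correlation and fry were alternatives. The lists, the contrasts and the alternatives were fixed before the data were examined. Overlaps were tested with Fisher's exact test.

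Genes were named by a rule. RUVBL1 and RUVBL2 are given per library, with the called members of the R2TP list. For each knockdown the rule took the 8 highest and 8 lowest log2 fold changes among called genes with a symbol, a mean of at least 5 CPM over the line's 4 libraries and both knockdown libraries on the same side of both controls. For each list it took up to 4 called members with the largest absolute log2 fold change. For the difference it took the 6 highest and 6 lowest with at least 5 CPM over 8 libraries, and for genes called in both lines the 6 largest rises and falls by the smaller of the folds. For the control groups it took members of the lineage lists. Fewer are named where a part of the rule gives many, and a gene singled out in another way is said to have been chosen after its values were seen. Some genes that the rule gives are not reported here.

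The alternatives were DESeq2, limma-trend on log2 of the deposited FPKM plus 1, effective lengths as offsets, RLE scaling, library totals only, no filter, a stricter filter (50 counts in 2 libraries), an adjusted p of 0.01, a fold of at least 2, libraries thinned to 16885991 counts, separate fits of each line, the replicate number as a block, and each library left out in turn.

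Technical explanations were tested with genes outside a list matched on GC content, length and CPM, and with a test of all 16384 heptamers in annotated 3′ UTRs against the mean log2 fold change of the 2 lines, after a regression on 3′ UTR length and GC content. The length used for matching was changed to the RSEM effective length, and the set of RUVBL1 heptamers was narrowed to protein-coding transcripts, after a first result had been seen. A test of library scaling that subtracted the median of all genes was left out, since the subtraction fixes its outcome.

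A self-test with simulated counts of 17776 genes changed 100 genes by each fold. In BPH1 80% of the 2-fold and 58% of the 1.5-fold changes were found with 12 false calls, in PC3 60% and 56% with 16, and between the control groups 71% and 55% with 13. For the difference the shares were 71% and 43% with 23 false calls when BPH1 was changed, and 55% and 40% with 14 when PC3 was changed. Over both folds, true calls numbered 138 in BPH1, 116 in PC3 and 126 between the control groups. For the difference they numbered 114 when BPH1 was changed and 95 when PC3 was changed. In each case the false share of the calls was above the rate that the adjusted p threshold states. The counts of called genes may thus hold a larger false share than that threshold states. Each simulation changed 200 genes, far fewer than were called in the data, so its false share does not carry over as a value. Camera found 20 of 20 lists of 20 genes shifted 1.2-fold and 0 of 20 lists that were not shifted, with the preset and with the estimated correlation. The simulated genes were drawn independently, so this does not show the error rate for lists whose members are correlated.

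Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.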

Results

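Gene expression was profiled by RNA-seq in 2 human prostate cell lines, BPH1, an epithelial line immortalized from benign hyperplastic tissue, and PC3, a prostate carcinoma line. Lentiviral vectors had delivered either a control short hairpin RNA (shRNA) or an shRNA against RUVBL1, and each of the 4 groups held 2 libraries. RUVBL1 is an ATPase that works with RUVBL2 in the INO80, SRCAP and TIP60 chromatin complexes and in the R2TP co-chaperone. The 8 libraries held 19865819 and 19907959 expected counts in the BPH1 control, 16886030 and 18894695 in the BPH1 knockdown, 18742960 and 19138823 in the PC3 control, and 20970962 and 20245230 in the PC3 knockdown. Levels are given as CPM (counts scaled to library size), as mean ± SD of 2 libraries, and log2 fold changes are given ± SE. Adjusted p-values of genes are from edgeR's quasi-likelihood test and those of gene lists from camera. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

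The knockdown was checked first in every library. RUVBL1 (ENSG00000175792, GRCh38 chromosome 3, 128064778 to 128153914, minus strand) stood at 162.9 and 167.1 CPM in the BPH1 control libraries and at 18.5 and 19.2 CPM in the BPH1 knockdown libraries. In PC3 it stood at 65.7 and 59.6 CPM in the controls and at 18 and 18.9 CPM after knockdown. The log2 fold change of RUVBL1 was −3.13 ± 0.08 in BPH1 (adjusted p = 7.71e-14) and −1.76 ± 0.08 in PC3 (adjusted p = 4.09e-09). The fold was smaller in PC3 by 1.36 ± 0.11 on the log2 scale (adjusted p of the difference = 2.68e-07), and the PC3 control held less RUVBL1 than the BPH1 control (log2 difference −1.40, adjusted p = 9.7e-12). An antisense gene, RUVBL1-AS1, overlaps the locus, and the strand used in counting is not given in the sources used here.

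**Figure D1:**
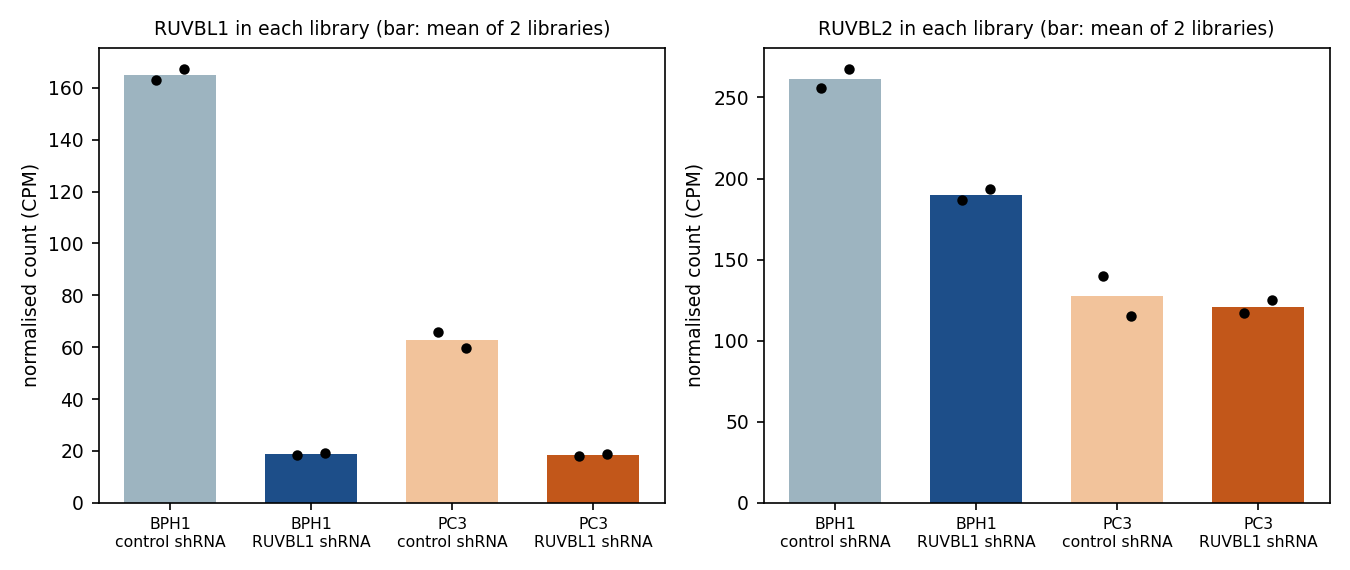
RUVBL1 and RUVBL2 in CPM in each of the 8 libraries, with bars at the mean of 2 libraries per group. RUVBL1 lies between 18 and 19.2 CPM in the 4 knockdown libraries, against at least 59.6 CPM in the 4 controls.

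RUVBL2, the partner ATPase, fell in BPH1 by 0.46 on the log2 scale, from 261.5 ± 8.28 to 190.1 ± 4.85 CPM (adjusted p = 1.29e-04). In PC3 its log2 fold change was −0.07 (adjusted p = 0.543), and it was 0.05 without replicate 1 of the PC3 control (adjusted p = 0.603) and −0.22 without replicate 2 (adjusted p = 0.0115). Among R2TP and prefoldin-like co-chaperone genes, PDRG1 rose in both lines, by 0.41 in BPH1 and 0.95 in PC3 (adjusted p = 1.2e-04 and 8.94e-08). PIH1D1, a core R2TP subunit, fell by 0.42 in PC3 (adjusted p = 5.31e-04). In BPH1 the log2 fold changes of PIH1D1, RPAP3, UXT and TTI1 were −0.22, −0.29, −0.34 and −0.19. Each of these 4 passed the test with all libraries and lost its call without 1 BPH1 library, with adjusted p of 0.231 for PIH1D1 and 0.119 for RPAP3 without control replicate 1, 0.186 for RPAP3 and 0.111 for UXT without knockdown replicate 2, and 0.102 for UXT and 0.281 for TTI1 without control replicate 2. PIH1D1 and TTI1 also lost it without knockdown replicate 1 (0.139 and 0.193) and without knockdown replicate 2 (0.112 and 0.111). The list as a whole did not pass in BPH1, where 1 of 14 genes rose and 5 fell (6 passed adjusted over the list alone, camera adjusted p = 0.174), nor in PC3 (1 rose and 1 fell, 2 adjusted over the list alone, camera adjusted p = 0.837).

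The series was designed to compare the transcriptional changes that follow RUVBL1 knockdown, and BPH1 is taken first. In BPH1, the lists of inflammatory genes, TGF-beta and YAP/TAZ targets and mesenchymal markers passed the camera test as higher, and those of mitosis, ribosomal proteins and the respiratory chain as lower. Members of a list did not all move, and 0 lists passed with an estimated correlation (adjusted p from 0.117 to 0.348 for these). KRT34, a hair keratin, rose from 1.67 ± 0.038 to 99.7 ± 0.176 CPM (log2 fold change 5.89 ± 0.14, adjusted p = 7.71e-14). IGF2, a growth factor, rose from 0.848 ± 0.449 to 16.1 ± 0.928 CPM (4.24 ± 0.20, adjusted p = 1.59e-10), and ESM1, a secreted proteoglycan, from 1.43 ± 0.301 to 31.1 ± 2.66 CPM (4.43 ± 0.17, adjusted p = 1.48e-11). NEFL, the light neurofilament subunit, fell from 274 ± 1.01 to 66.9 ± 5.1 CPM (−2.04 ± 0.06, adjusted p = 5.85e-13). Of 17776 genes tested, 6280 (35.3%) passed an adjusted p of 0.05, 3215 higher and 3065 lower. A fold of at least 2 was reached by 1084 of them, 715 higher and 369 lower.

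Other large rises in BPH1 were those of CRCT1 (0.292 ± 0.112 to 15.7 ± 0.492 CPM), C15orf48 (1.51 ± 0.187 to 28.4 ± 1.04 CPM), KRTAP2-3, a keratin-associated protein (3.55 ± 0.373 to 72.75 ± 0.677 CPM), the unitary pseudogene MYH16 (log2 fold change 4.64) and the long noncoding RNA LINC01127 (4.12). Keratin and keratin-associated genes belong to families of similar members, so the split of reads between KRT34 or KRTAP2-3 and their neighbours is uncertain. Other large falls were those of ALDH3A1, an aldehyde dehydrogenase (log2 fold change −2.59), PRAC1 (−2.31), CBLN1 (−2.26), VAV3, a guanine nucleotide exchange factor (−2.23), and SYT12 (−2.14). Both knockdown libraries lay on the same side of both controls for 67.8% of all genes tested in BPH1 and 56.9% in PC3, where chance alone gives 33.3%.

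Of 17 NF-kB and inflammatory genes tested in BPH1, 15 rose and 1 fell (16 adjusted over the list alone), with a median log2 fold change of 1.51 (camera adjusted p = 2.42e-08, adjusted p = 0.117 with an estimated correlation). The cytokine CSF2 rose by 3.40, the chemokine CXCL8 by 3.22 (12.5 ± 0.93 to 117 ± 0.527 CPM), the prostaglandin synthase PTGS2 by 2.68 (68.8 ± 2.25 to 441 ± 0.627 CPM) and IL1B by 2.34. Of 29 TGF-beta/SMAD target genes, 18 rose and 8 fell (26 adjusted over the list alone), with a median of 0.85 (camera adjusted p = 1.54e-04, adjusted p = 0.207 with an estimated correlation). TAGLN, an actin-binding protein, rose by 3.15. Of 10 YAP/TAZ targets, 7 rose and 3 fell (10 adjusted over the list alone). Their median was 1.07 (camera adjusted p = 0.00742, adjusted p = 0.207 with an estimated correlation). NT5E, ANKRD1 and CCN2 rose by 2.38, 2.23 and 1.43.

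Of 14 mesenchymal markers tested in BPH1, 8 rose and 2 fell (11 adjusted over the list alone). Their median was 0.49 (camera adjusted p = 0.0117, adjusted p = 0.207 with an estimated correlation). FN1, encoding fibronectin, rose from 670 ± 35 to 4777 ± 28.1 CPM (log2 fold change 2.83), and LOX and VIM rose by 1.84 and 1.72. Of 19 epithelial junction and keratin genes, 12 rose and 4 fell (16 adjusted over the list alone). Their median was 0.41 (camera adjusted p = 0.00482, adjusted p = 0.207 with an estimated correlation). The tight junction genes CLDN4 and OCLN rose by 1.55 and 1.26. All 12 genes of ER chaperones and the unfolded protein response rose (12 adjusted over the list alone). Their median was 0.44 (camera adjusted p = 5.45e-06, adjusted p = 0.207 with an estimated correlation). DNAJB9 rose by 1.12 and HSP90B1 by 0.62. Of 13 immediate early and AP-1 genes, 10 rose and 1 fell (11 adjusted over the list alone). Their median was 0.56 (camera adjusted p = 2.91e-04, adjusted p = 0.207 with an estimated correlation). KLF6 rose by 2.10 and ATF3 by 1.22.

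Mitotic genes fell in BPH1. All 26 G2/M genes tested were lower (26 adjusted over the list alone), with a median log2 fold change of −0.49 (camera adjusted p = 1.3e-11, adjusted p = 0.207 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell from 498 ± 21.5 to 246 ± 5.15 CPM (−1.02). The spindle assembly factor TPX2 and the kinesin KIF20A had log2 fold changes of −0.97 and −0.91. Of 28 genes of G1/S and DNA replication, 3 rose and 12 fell (16 adjusted over the list alone). Their median was −0.17 (camera adjusted p = 0.00742, adjusted p = 0.207 with an estimated correlation). POLA1, the catalytic subunit of DNA polymerase alpha, had a log2 fold change of −1.41 and RRM2 of −0.97, while the replication factor GINS3 rose by 0.96. Of 12 heat shock genes, 2 rose and 10 fell (12 adjusted over the list alone). Their median was −0.31 (camera adjusted p = 0.00742, adjusted p = 0.228 with an estimated correlation). CHORDC1 and HSPA8 had log2 fold changes of −0.66 and −0.48, and DNAJB1 rose by 0.499.

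Of 40 cytosolic ribosomal protein genes, 34 fell in BPH1 and 0 rose (37 adjusted over the list alone), with a median log2 fold change of −0.22 (camera adjusted p = 2.39e-08, adjusted p = 0.348 with an estimated correlation). RPS4X and RPS6 had log2 fold changes of −0.38 and −0.36, and ribosomal protein genes have many processed pseudogenes that could share their reads. Genes outside the list, matched on GC content, length and CPM, had a median of −0.15 (200 genes, 95% interval −0.20 to −0.11). Only the 40 listed genes were kept out of that matched set, so other ribosomal protein genes could be in it. Of 24 nuclear-encoded respiratory chain genes, 16 fell and 0 rose (17 adjusted over the list alone). Their median was −0.23 (camera adjusted p = 5.48e-06, adjusted p = 0.207 with an estimated correlation), with −0.70 for ATP5PO and −0.45 for UQCRC1. The matched genes of that list had a median of −0.08. Of 26 ribosome biogenesis factors, 17 fell and 0 rose (17 adjusted over the list alone). Their median was −0.23 (camera adjusted p = 8.42e-04, adjusted p = 0.28 with an estimated correlation), with −0.55 for HEATR1 and −0.46 for NPM1. Of 19 MYC targets, 2 rose and 13 fell (15 adjusted over the list alone). Their median was −0.23 (camera adjusted p = 0.00183, adjusted p = 0.316 with an estimated correlation), with −0.74 for IMPDH2 and −0.52 for LDHA. Of 13 mitochondrially encoded mRNAs, 1 rose and 10 fell (11 adjusted over the list alone). Their median was −0.26 (camera adjusted p = 0.00328, adjusted p = 0.442 with an estimated correlation). Mitochondrial genes took 3.06% and 3.08% of counts in the BPH1 controls and 2.55% in each knockdown library.

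Of the 40 lists, 18 passed in BPH1, and 3 of these lost their call when single libraries were left out. Of 22 interferon-stimulated genes, 9 rose and 3 fell (13 adjusted over the list alone). Their median was 0.14 (camera adjusted p = 0.0391, adjusted p = 0.442 with an estimated correlation). IFI27 rose by 1.79 and IFI6 rose too (31.89 ± 0.879 to 90.4 ± 9.57 CPM). The list's adjusted p was 0.0645 without replicate 1 of the BPH1 control, 0.0537 without either PC3 control library and 0.052 without either PC3 knockdown library. Of 19 extracellular matrix genes, 8 rose and 3 fell (11 adjusted over the list alone). Their median was 0.05 (camera adjusted p = 0.0441, adjusted p = 0.506 with an estimated correlation), with an adjusted p of 0.128 without replicate 1 of the BPH1 control, 0.0976 without replicate 2 of the BPH1 knockdown, 0.0663 without either PC3 control library and 0.052 without either PC3 knockdown library. Of 18 TGF-beta and BMP pathway components, 6 rose and 1 fell (7 adjusted over the list alone). Their median was 0.09 (camera adjusted p = 0.0442, adjusted p = 0.454 with an estimated correlation). The receptor TGFBR2 rose by 1.32 and TGFBR1 by 0.98. That list stood at 0.0685 without replicate 2 of the BPH1 control, 0.0627 without replicate 1 of the BPH1 knockdown, 0.0731 without either PC3 control library, 0.0572 without either PC3 knockdown library and 0.0612 with library totals only.

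Lists of chromatin complexes that hold RUVBL1 and of PIKK family kinases did not pass in BPH1. Of 32 genes of the INO80, SRCAP and TIP60 complexes, 7 rose and 6 fell (13 adjusted over the list alone, camera adjusted p = 0.743), and of 6 PIKK family kinases, 1 rose and 4 fell (5 adjusted over the list alone, camera adjusted p = 0.335). Of 21 p53 targets, 7 rose and 4 fell (12 adjusted over the list alone, camera adjusted p = 0.226). GADD45A and CDKN1A, a growth arrest gene and a cyclin-dependent kinase inhibitor, rose by 1.74 and 1.25, and FDXR fell by 0.84. Markers of fibroblasts and smooth muscle, endothelial cells and immune cells had camera adjusted p of 0.908, 0.743 and 0.743 in BPH1 and 0.478, 0.376 and 0.884 in PC3, over 6, 3 and 4 genes tested.

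In PC3, the lists of interferon-stimulated and mitotic genes passed the camera test as lower, and those of the amino acid response and of cholesterol synthesis as higher. With an estimated correlation 0 lists passed (adjusted p from 0.105 to 0.328 for these). All 22 interferon-stimulated genes tested were lower (22 adjusted over the list alone), with a median log2 fold change of −1.23 (camera adjusted p = 3.87e-17, adjusted p = 0.105 with an estimated correlation). MX1, an antiviral GTPase, fell from 46.7 ± 5.92 to 16.7 ± 0.714 CPM (−1.48 ± 0.10, adjusted p = 1.12e-07), and IFITM1, a membrane protein that limits viral entry, from 25.9 ± 0.388 to 6.96 ± 0.477 CPM (−1.90 ± 0.12, adjusted p = 8.76e-08). The log2 fold changes of MX2, IFIT1, IFI27 and IFI44 were −1.98, −1.58, −1.55 and −1.48. The summed level of the list was 935 and 967 CPM in the PC3 controls and 518 and 507 CPM after knockdown, and 682 and 712 CPM in the BPH1 controls and 994 and 962 CPM after knockdown.

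Of 17776 genes, 3695 (20.8%) passed in PC3, 1806 higher and 1889 lower, and 301 reached a fold of at least 2, 187 higher and 114 lower. The higher share of the calls was 48.9%, and it was 41.2% with RLE scaling, 39% with DESeq2 and 60.7% with limma on FPKM values. The count was 2162 without replicate 1 and 2029 without replicate 2 of the PC3 knockdown. GUCA1B rose from 1.82 ± 0.072 to 11.3 ± 0.287 CPM (log2 fold change 2.63 ± 0.21, adjusted p = 8.29e-07), CLDN15, a claudin, from 7.20 ± 0.182 to 20.2 ± 0.102 CPM (1.49 ± 0.14), and RASSF1 from 35.4 ± 2.2 to 83.5 ± 0.821 CPM (1.24 ± 0.09). DLL4, a Notch ligand, rose by 1.22. The readthrough locus NME1-NME2 rose by 2.05, but it shares exons with the genes it joins, so its reads are uncertain. DHRS2, a short-chain dehydrogenase, fell from 20.1 ± 0.691 to 6.18 ± 0.944 CPM (−1.70 ± 0.12, adjusted p = 1.47e-07), and HEPHL1 from 31.3 ± 0.285 to 10.8 ± 0.978 CPM (−1.53 ± 0.10).

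Of 26 G2/M genes, 21 fell and 0 rose in PC3 (21 adjusted over the list alone). Their median was −0.36 (camera adjusted p = 9.95e-10, adjusted p = 0.328 with an estimated correlation), with −0.71 for KIF20A, −0.51 for CCNB1 and −0.502 for CDC20. Of 16 genes of ATF4 and the amino acid response, 12 rose and 1 fell (14 adjusted over the list alone). Their median was 0.43 (camera adjusted p = 2.44e-06, adjusted p = 0.105 with an estimated correlation). The stress-induced transcription factors ATF3 and DDIT3 rose by 1.25 and 1.15, from 13.1 ± 0.86 to 31.2 ± 0.592 CPM and from 20.8 ± 1.13 to 46.1 ± 1.56 CPM, and SESN2 rose by 0.92. Of 20 genes of cholesterol synthesis and uptake, 10 rose and 0 fell (12 adjusted over the list alone). Their median was 0.23 (camera adjusted p = 5.3e-05, adjusted p = 0.236 with an estimated correlation). SREBF2, a transcription factor of the pathway, rose by 0.70.

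Of 15 snoRNA host genes and RNAs subject to nonsense-mediated decay, 10 rose and 1 fell in PC3 (11 adjusted over the list alone). Their median was 0.33 (camera adjusted p = 0.00221, adjusted p = 0.236 with an estimated correlation). EPB41L4A-AS1 rose by 0.97 and GADD45B by 0.82. Of 12 heat shock genes, 5 fell and 0 rose (9 adjusted over the list alone). Their median was −0.16 (camera adjusted p = 0.00951, adjusted p = 0.328 with an estimated correlation), with −0.28 for HSP90AB1 and −0.26 for HSPA8. Of 29 TGF-beta/SMAD target genes, 11 rose and 3 fell (16 adjusted over the list alone). Their median was 0.16 (camera adjusted p = 0.0125, adjusted p = 0.328 with an estimated correlation). The cytokine IL11 rose by 1.09, while ANGPTL4 fell by 0.86. In PC3, 5 of 32 genes of the INO80, SRCAP and TIP60 complexes rose and 4 fell (11 adjusted over the list alone, camera adjusted p = 0.17).

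Of the 12 lists that passed in PC3, 5 lost their call when single libraries were left out. Of 13 immediate early and AP-1 genes, 5 rose and 0 fell (8 adjusted over the list alone). Their median was 0.30 (camera adjusted p = 0.00527, adjusted p = 0.328 with an estimated correlation, and 0.0661 without replicate 2 of the PC3 control). Of 24 respiratory chain genes, 7 fell and 0 rose (7 adjusted over the list alone). Their median was −0.09 (camera adjusted p = 0.0125, adjusted p = 0.387 with an estimated correlation, and 0.05 without replicate 1 of the PC3 knockdown), with −0.48 for SDHA and −0.47 for UQCRC2. Of 10 genes near RUVBL1, 7 rose and 0 fell (7 adjusted over the list alone). Their median was 0.18 (camera adjusted p = 0.0125, adjusted p = 0.328 with an estimated correlation), with 0.0855 without replicate 2 of the PC3 control and 0.0702 without replicate 2 of the PC3 knockdown. RPN1 rose by 0.31. Of 14 lysosome and autophagy genes, 6 rose and 1 fell (7 adjusted over the list alone). Their median was 0.17 (camera adjusted p = 0.0375, adjusted p = 0.328 with an estimated correlation), with an adjusted p of 0.131 without replicate 2 of the PC3 control, 0.05 and 0.0879 without replicates 1 and 2 of the PC3 knockdown, 0.057 without either BPH1 control library, and 0.0587 and 0.0588 without replicates 1 and 2 of the BPH1 knockdown. Of 40 ribosomal protein genes, 7 rose and 1 fell (8 adjusted over the list alone). Their median was 0.07 (camera adjusted p = 0.046, adjusted p = 0.844 with an estimated correlation). That call held without replicate 1 of the PC3 knockdown and was lost without each of the other 7 libraries, at 0.321 and 0.0799 without replicates 1 and 2 of the PC3 control, 0.522 without replicate 2 of the PC3 knockdown, 0.0739 without either BPH1 control library, and 0.0659 and 0.066 without replicates 1 and 2 of the BPH1 knockdown.

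**Figure D2:**
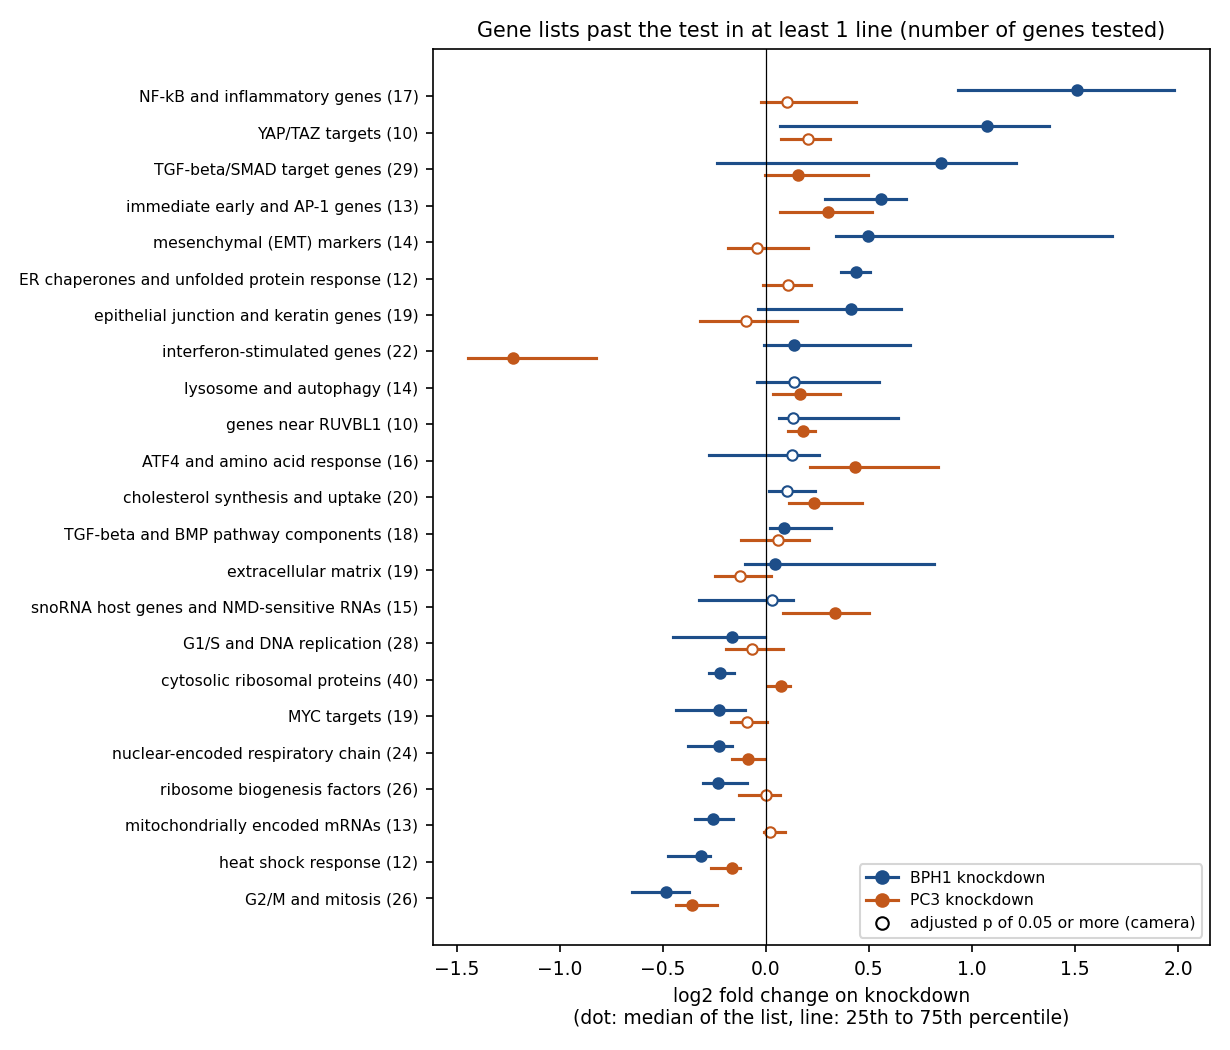
Gene lists that passed the camera test in at least 1 line, with the median log2 fold change of the tested members on knockdown (dot) and their 25th to 75th percentile (line) in BPH1 and PC3, where an open dot marks an adjusted p of 0.05 or more. The interferon-stimulated genes lie at −1.23 in PC3 and 0.14 in BPH1, and the G2/M genes at −0.36 and −0.49.

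The responses of the lines were then set side by side, each line having its own controls. FKBP5, an HSP90 co-chaperone, fell in both, from 41.7 ± 0.547 to 14.04 ± 1 CPM in BPH1 and from 20 ± 0.333 to 9.49 ± 0.974 CPM in PC3 (log2 fold changes −1.57 and −1.08). Falls in both lines were also found for TRIM14 (−1.16 in BPH1 and −1.01 in PC3), SVBP, a partner of vasohibins (−1.86 and −1.45), the noncoding RNA SNHG4 (−1.14 and −1.13), and the interferon-induced OASL (−1.03 and −1.30). HSD17B10, a mitochondrial dehydrogenase, rose from 21.9 ± 0.649 to 68.4 ± 1.53 CPM in BPH1 and from 38.9 ± 0.404 to 87.7 ± 8.7 CPM in PC3 (1.64 and 1.17). ATF3 rose by 1.22 and 1.25, ST6GAL2, a sialyltransferase, by 1.69 and 1.16, and the urea transporter SLC14A1 by 2.19 and 1.15. Of 7835 genes called in either line, 2140 were called in both, 1758 in 1 direction (82.1%) and 382 in opposite directions. Genes higher in both numbered 860 against 326.6 for independent calls (odds ratio 5.26, two-sided Fisher's exact test p = 1.12e-207), and genes lower in both 898 against 325.7 (5.74, p = 5.7e-235). Those higher in BPH1 and lower in PC3 numbered 272 against 341.6 (odds ratio 0.74), and those lower in BPH1 and higher in PC3 110 against 311.4 (0.286). Genes are not independent replicates, and across all genes tested the log2 fold changes of the lines had a Pearson r of 0.108 and a Spearman rho of 0.253. The count of genes called in 1 direction was 1105 and 1060 without replicates 1 and 2 of the PC3 knockdown, and the count in opposite directions was 240 and 229 without these and 253 and 245 without replicates 1 and 2 of the BPH1 knockdown.

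**Figure D3:**
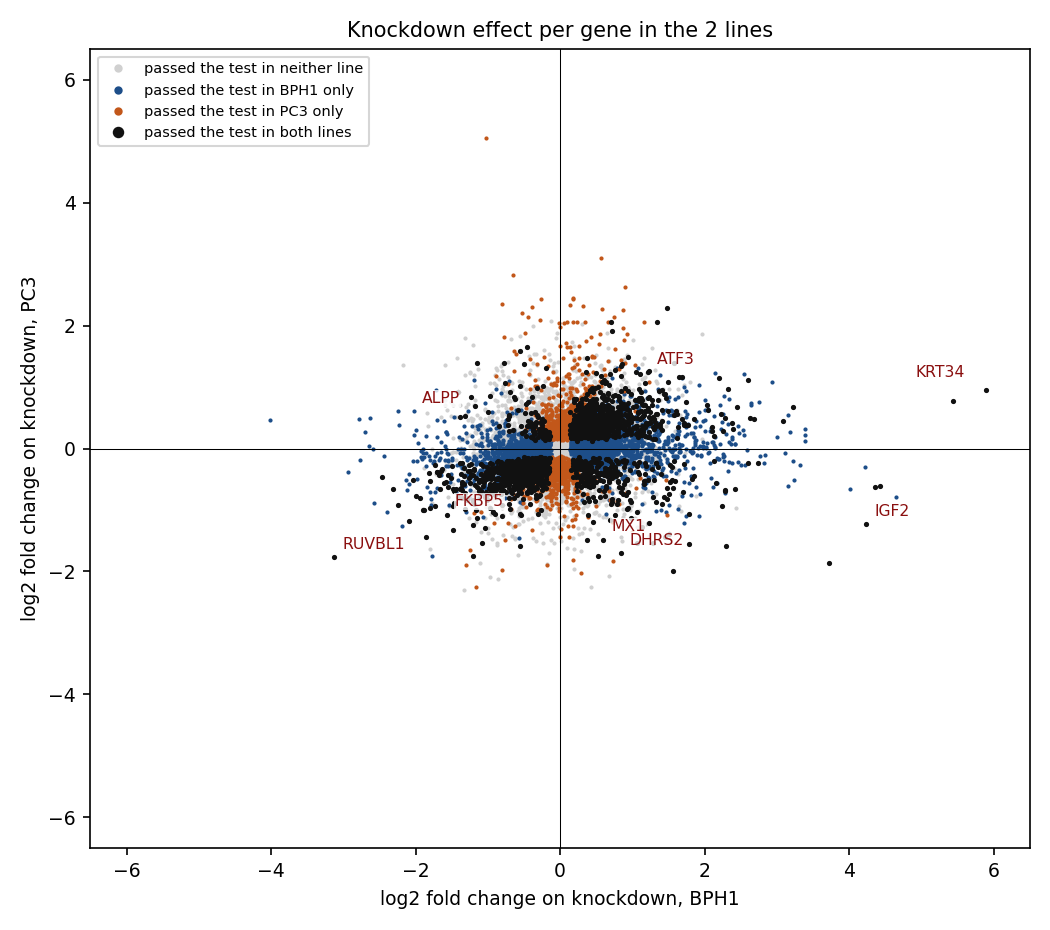
Log2 fold change on RUVBL1 knockdown in BPH1 (horizontal) and in PC3 (vertical) for 15702 genes, coloured by whether they passed the test in neither line, in BPH1, in PC3 or in both. The 2074 genes with under 3 counts per library in a group are not drawn, RUVBL1 lies at −3.13 and −1.76, and IGF2 and MX1 lie on opposite sides of 0 in the 2 lines.

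The difference between the lines was tested directly, as the PC3 effect less the BPH1 effect. RUVBL1 itself fell less in PC3 (−1.76) than in BPH1 (−3.13). The level left after knockdown was alike, at 18.5 and 19.2 CPM in BPH1 and 18 and 18.9 CPM in PC3, and the PC3 controls started lower. The design therefore cannot separate the line from the fold of the knockdown as the source of a difference. IGF2 rose in BPH1 and fell in PC3, from 44.1 ± 0.51 to 18.8 ± 0.179 CPM (difference −5.47 ± 0.22, adjusted p = 1.4e-10), and ESM1 rose in BPH1 and fell in PC3 from 124.7 ± 11 to 81.9 ± 7.05 CPM (−5.04 ± 0.19, adjusted p = 4.85e-11). KRTAP2-3, KRT34 and C15orf48 differed by −4.98, −4.93 and −4.53. ALPP, placental alkaline phosphatase, fell in BPH1 from 101.5 ± 2.53 to 24.97 ± 1.98 CPM and stood at 0.774 ± 0.192 and 1.18 ± 0.033 CPM in PC3 (difference 2.63 ± 0.31, adjusted p = 1.53e-05). Of 22 interferon-stimulated genes, 19 had a lower fold change in PC3 than in BPH1 and 0 a higher one (20 adjusted over the list alone). Their median was −1.38 (camera adjusted p = 4.28e-14, adjusted p = 0.104 with an estimated correlation). MX1 and DHRS2 fell in PC3 and rose in BPH1 (differences −2.07 and −2.55).

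The difference passed for 3328 genes (18.7%), 1484 higher (44.6%) and 1844 lower, and 771 reached a fold of at least 2. The higher share was 55.2% with library totals only and 33.9% with DESeq2, and the count was 2175 and 2179 without replicates 1 and 2 of the BPH1 knockdown. Of the 12 genes that the naming rule gives for the difference (the 6 highest and 6 lowest with at least 5 CPM over 8 libraries), 5 (EPHA5, PPP2R2B, CYBA, TSPAN8 and WDR72) had a group under 3 counts per library and are given no fold. ZACN differed by 6.08, but its knockdown libraries were far apart in both lines, at 6.04 ± 7 CPM in BPH1 and 5.96 ± 5.09 CPM in PC3, and its adjusted p was 0.0741 with limma on FPKM values.

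Inflammatory genes had lower fold changes in PC3 than in BPH1, with 11 of 17 lower and 1 higher in the difference (16 adjusted over the list alone). Their median was −1.30 (camera adjusted p = 7.13e-08, adjusted p = 0.104 with an estimated correlation). PTGS2, CXCL8 and IL1B differed by −2.20, −2.54 and −2.23. Of 19 epithelial junction genes, 12 were lower and 0 higher (17 adjusted over the list alone). Their median was −0.35 (camera adjusted p = 5.27e-05, adjusted p = 0.104 with an estimated correlation), with −1.40 for CLDN4. Of 40 ribosomal protein genes, 37 were higher in the difference and 0 lower (38 adjusted over the list alone). Their median was 0.28 (camera adjusted p = 1.09e-10, adjusted p = 0.339 with an estimated correlation). Genes outside that list, matched on GC content, length and CPM, had medians of −0.15 in BPH1 and 0.02 in PC3. The matched genes thus differed between the lines in the same direction. They could include ribosomal protein genes that are not on the list, so no conclusion is drawn from this. Of 16 genes of the ATF4 list, 8 were higher and 2 lower (11 adjusted over the list alone). Their median was 0.49 (camera adjusted p = 6.71e-04, adjusted p = 0.153 with an estimated correlation), with 1.03 for DDIT3 and 0.79 for SESN2. Of 29 TGF-beta/SMAD target genes, 6 were higher and 18 lower (24 adjusted over the list alone). Their median was −0.57 (camera adjusted p = 5.09e-04, adjusted p = 0.231 with an estimated correlation). Of 26 G2/M genes, 7 were higher and 0 lower (7 adjusted over the list alone). Their median was 0.18 (camera adjusted p = 5.09e-04, adjusted p = 0.401 with an estimated correlation), with 0.54 for TPX2 and 0.52 for CDC20.

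The control groups were compared to describe the lines themselves. All 12 basal epithelial markers were lower in the PC3 control than in the BPH1 control, the smallest difference being −0.57 (12 adjusted over the list alone). Their median was −5.96 (camera adjusted p = 2.38e-06, adjusted p = 0.0698 with an estimated correlation). KRT5, a basal keratin, stood at 5342 ± 101 CPM in BPH1 and 0 counts in both PC3 control libraries, at least 33701-fold lower against a floor of 3 counts per library. KRT17 stood at 1481 ± 165 against 0.30 ± 0.147 CPM, and the basal transcription factor TP63 at 196.6 ± 6.6 against 0.174 ± 0.032 CPM. Of 19 epithelial junction and keratin genes, 17 were lower in PC3 and 2 higher (19 adjusted over the list alone). Their median was −2.53 (camera adjusted p = 3.67e-06, adjusted p = 0.0698 with an estimated correlation), with CDH1, encoding E-cadherin, at 311 ± 0.132 against 10.3 ± 0.105 CPM (−4.91). VIM, encoding vimentin, was higher in PC3 by 6.44 (21.5 ± 1.26 against 1867 ± 32.3 CPM) and the prostate homeobox gene HOXB13 by 5.83 (11.3 ± 0.894 against 645 ± 34.6 CPM). Their lists did not pass, with 8 of 14 mesenchymal markers higher and 5 lower (13 adjusted over the list alone, camera adjusted p = 0.502), and 6 of 9 prostate luminal and androgen receptor genes higher and 3 lower (9 adjusted over the list alone, camera adjusted p = 0.238).

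Of 28 genes of G1/S and DNA replication, 27 were lower in the PC3 control and 1 higher (28 adjusted over the list alone). Their median was −0.99 (camera adjusted p = 1.84e-06, adjusted p = 0.0698 with an estimated correlation). Of 40 ribosomal protein genes, 34 were lower and 6 higher (40 adjusted over the list alone). Their median was −1.06 (camera adjusted p = 3.05e-06, adjusted p = 0.658 with an estimated correlation). Of 16 replication-dependent histone genes, 14 were higher and 0 lower (14 adjusted over the list alone). Their median was 2.48 (camera adjusted p = 1.1e-04, adjusted p = 0.262 with an estimated correlation), with 3.85 for H2AC6. Of 14 homologous recombination and Fanconi genes, 11 were lower and 0 higher (11 adjusted over the list alone). Their median was −1.23 (camera adjusted p = 0.00349, adjusted p = 0.629 with an estimated correlation). Of 26 G2/M genes, 20 were lower and 3 higher (23 adjusted over the list alone). Their median was −0.52 (camera adjusted p = 0.00344, adjusted p = 0.712 with an estimated correlation). In all, 13382 genes (75.3%) passed, 6650 higher and 6732 lower in PC3, 7185 with a fold of at least 2, and the median of all genes moved up by 0.16 with library totals only.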

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

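The 3 tests of technical explanations in this part were chosen after the result was seen, and the tests of the difference between the lines were planned. Each result here is listed because the knockdown effect differed between the lines when the difference itself was tested. That held for 3328 genes, and 382 genes were called in both lines in opposite directions. Opposite calls were fewer than independent calls would give, at 272 against 341.6 for higher in BPH1 and lower in PC3. The reverse class held 110 against 311.4.

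RUVBL1 itself differed by 1.36, RUVBL2 by 0.39 and PDRG1 by 0.55 on the log2 scale, each as the PC3 effect less the BPH1 effect. The fold of the knockdown was thus smaller in PC3, where the control level was lower, and that fold cannot be told apart from the line in the differences listed here. The RUVBL2 difference had an adjusted p of 0.0167 with all libraries and lost its call without BPH1 control replicate 2 (0.0765), BPH1 knockdown replicate 1 (0.0975) or 2 (0.0585), or PC3 knockdown replicate 2 (0.0952). Genes with a rise in BPH1 had negative differences, KRT34 −4.93, MYH16 −5.44, ESM1 −5.04, KRTAP2-3 −4.98, IGF2 −5.47 and C15orf48 −4.53. Genes with a fall in BPH1 had positive differences, ALDH3A1 2.58, PRAC1 1.66, VAV3 2.62, SYT12 1.62, NEFL 1.53 and ALPP 2.63. Genes with a rise in PC3 were GUCA1B 1.73, NME1-NME2 1.71, CLDN15 1.05, RASSF1 0.88 and ZACN 6.08. Genes with a fall in PC3 were IFITM1 −1.71, DHRS2 −2.55, IFIT1 −1.02, IFI27 −3.34, HEPHL1 −2.82, MX1 −2.07 and IFI44 −1.86. Among genes called in both lines, HSD17B10 differed by −0.47, SLC14A1 by −1.04 and FKBP5 by 0.50. The FKBP5 difference lost its call without either BPH1 control library (0.0638 and 0.078), without BPH1 knockdown replicate 2 (0.13) and without PC3 knockdown replicate 2 (0.17).

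Among gene lists, the median differences were −1.38 for interferon-stimulated genes, −1.30 for NF-kB and inflammatory genes, −0.82 for YAP/TAZ targets, −0.70 for mesenchymal markers, −0.57 for TGF-beta/SMAD target genes, −0.40 for ER chaperones, −0.35 for epithelial junction and keratin genes, −0.30 for extracellular matrix, −0.11 for immediate early and AP-1 genes, and −0.062 for TGF-beta and BMP pathway components. Positive medians were those of ATF4 and amino acid response genes (0.49), cytosolic ribosomal proteins (0.28), mitochondrially encoded mRNAs (0.26), snoRNA host genes and NMD-sensitive RNAs (0.26), ribosome biogenesis factors (0.21), MYC targets (0.21), G2/M and mitosis (0.18), the nuclear-encoded respiratory chain (0.16), G1/S and DNA replication (0.15), and snoRNP and telomerase assembly (0.13). For MYC targets the mean was −0.02, since CCND2 went from 0.225 to 0.023 CPM in PC3. Of these lists 6 lost their call when single libraries were left out. The highest adjusted p was 0.0649 for G1/S without BPH1 control replicate 2, 0.0773 for MYC targets and 0.0679 for the respiratory chain without PC3 knockdown replicate 2, 0.146 for TGF-beta and BMP pathway components without PC3 control replicate 2, 0.161 for snoRNP and telomerase assembly without PC3 knockdown replicate 1, and 0.131 for immediate early and AP-1 genes without PC3 control replicate 1. Camera with an estimated correlation passed 0 lists.

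Interferon-stimulated genes fell in PC3, with a median of −1.23. In BPH1, 9 of 22 rose, 3 fell and 10 were not called, with a median of 0.14, and the list call was lost with any of 5 single libraries left out (adjusted p from 0.052 to 0.0645). A single PC3 control library with high levels is argued against, since the median was −1.07 or lower with any 1 PC3 library left out. GC content and transcript length are argued against as well, since matched genes had a median of −0.039 (95% interval −0.125 to 0.038). A biological reading is that RUVBL1 loss lowered a basal interferon response in PC3. It could also be that the control hairpin raised that response in PC3, and no libraries of untransduced cells were analysed here, so the choice stays open.

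Ribosomal protein mRNAs fell in BPH1, with a median of −0.22. The median was −0.219 with RLE scaling and −0.256 with library totals only. Matched genes also had a median of −0.15 (95% interval −0.20 to −0.11), but ribosomal protein genes that are not on the list could be among them. The match therefore cannot decide, and GC content or transcript length stays open. The match was incomplete, with a median effective length of 544 against 477 bases and 335.6 against 627.4 CPM. As a description only, the Spearman rho of log2 fold change with effective length over 11852 genes was 0.134 in BPH1 and −0.0 in PC3. With GC content it was 0.052 and 0.004. A biological reading, lower ribosomal protein expression after RUVBL1 loss in BPH1, stays open beside GC content and length.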

How the results depend on the processing

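No alternative in this part was chosen after the result was seen, and no further tests were added. Of 605 calls of named genes, 450 kept their direction and side of the threshold under every alternative run for them. The call was lost under at least 1 for 155, and 4 turned. The stricter threshold and the required fold were not applied to these calls. DESeq2 covered 600 of them, the stricter filter 596 and the separate fits 308, so the rest were not checked there. Lists were rerun with the estimated correlation, fry, library totals, the replicate block and each library left out, and not with the other alternatives. Of 59 list calls, 43 were kept under all of these but the estimated correlation, and 0 turned.

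With limma-trend on FPKM the calls were 4072 in BPH1, 1592 in PC3 and 1875 for the difference, with 632 genes shared in 1 direction and 122 in opposite directions. With effective lengths as offsets they were 4127, 1608, 1650, 706 and 148. The cause was not tested for either. The stricter threshold of 0.01 gave 2111 in PC3, 1924 for the difference, 953 shared and 180 opposite. Requiring a fold of at least 2 gave 1084, 301, 771 and 7185 (control groups), 35 shared and 19 opposite, by its own construction. DESeq2, RLE scaling, library totals, both filters, thinned counts and separate fits stayed within 1.5 times for these counts, and separate fits were not run for the difference or the control groups.

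Camera with an estimated correlation passed 0 lists in BPH1, 0 in PC3, 0 for the difference and 0 between the control groups, and fry passed 31, 20, 25 and 33. The loss was not confined to lists with a high estimated correlation. In BPH1 the estimate was 0.341 for ribosomal proteins but −0.003 for NF-kB and inflammatory genes, under the preset of 0.01. The unadjusted camera p of the inflammatory list still went from 1.82e-09 to 0.00292. High correlation among members is thus argued against as the cause for that list, and other causes were not tested. Directions turned for BRCA2 (difference −0.012 with effective lengths, PC3 −0.203 with limma and −0.304 with effective lengths), COL17A1 (difference 0.037 with limma) and EPHA5 (difference −0.138 with limma). With fry, ER chaperones (0.0157) and immediate early genes (0.0366) took the opposite direction between the control groups. The cause was not tested.

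With each library left out in turn, a lone library of a group was assumed to vary like the other groups. The calls ranged from 4345 to 7066 in BPH1, 2029 to 3868 in PC3, 2175 to 3840 for the difference, 12476 to 13435 between the control groups, 1060 to 1984 shared and 229 to 491 opposite. RUVBL1 ranged from −3.158 to −3.1 in BPH1 and −1.845 to −1.71 in PC3, and RUVBL2 in PC3, which was not called with all libraries, from −0.219 without control replicate 2, where it was called (adjusted p = 0.0115), to 0.052 without control replicate 1. The cause was not tested.

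Deviations of libraries with the same replicate number correlated at −0.02 in BPH1 and 0.023 in PC3 over 17776 genes, so no shared replicate effect was seen. With 2 libraries per group this cannot show whether the samples were paired. With the replicate block the calls were 5740 in BPH1, 3089 in PC3, 2794 for the difference and 12165 between the control groups. Of 59 list calls the block ended 7, and it added 1. The ended calls included extracellular matrix in BPH1 (camera adjusted p = 0.0586) and TGF-beta and BMP pathway components in BPH1 (0.0644). Others were lysosome genes (0.0793) and ribosomal proteins (0.0967) in PC3, and immediate early genes in the difference (0.162). Thinning the libraries to 16885991 counts gave 6159, 3614, 3222 and 13125, so differences in depth changed these counts little.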

Other observations

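The tests of heptamer sites and of readthrough loci in this part were chosen, or in the rank test changed in its set of RUVBL1 heptamers, after the result was seen. KDR, a receptor of vascular endothelial growth factor, stood at 0.398 ± 0.038 CPM in the BPH1 control and 90.91 ± 0.16 CPM in the PC3 control, and fell in PC3 to 47.44 ± 0.006 CPM on knockdown (log2 fold change −0.94, edgeR adjusted p = 1.85e-06). In BPH1 it rose to 1.931 ± 0.79 CPM (2.24, edgeR adjusted p = 1.57e-04), a call lost with limma on FPKM values (adjusted p = 0.11). HEXA, a lysosomal hexosaminidase subunit chosen after its values were seen, stood at 86.46 ± 0.422 CPM in the BPH1 control and 0.101 ± 0.143 CPM in the PC3 control. Of 87 readthrough loci, 12 rose and 2 fell in PC3 (two-sided Fisher's exact test for rises, p = 0.282), and 11 rose and 7 fell in BPH1 (p = 0.21).

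The heptamer GCTTGCT had the lowest z of 16384 heptamers (−8.53) in a test of 3′ UTR sites in 11180 genes against the mean log2 fold change of the lines, and it lies in the coding sequence of RUVBL1 (GRCh38 chromosome 3, 128081370 to 128081376, minus strand). The next were CTTGCTA (−5.94) and TGCTTGC (−5.88), also in RUVBL1, and the lowest outside RUVBL1 was GGATCAC (−4.78). CTTGCTA and TGCTTGC overlap GCTTGCT in sequence and can share its sites, so they are not separate findings. RUVBL1 held 2595 heptamers, 15.8% of all, which is the chance that the lowest is one of them. Genes with a 3′ UTR site had a mean of −0.087 ± 0.01 against genes with none, −0.126 in BPH1 and −0.047 in PC3. The values per knockdown library were −0.122 and −0.127 in BPH1 and −0.046 and −0.046 in PC3, while control replicate 2 over replicate 1 gave −0.005 in BPH1 and −0.008 in PC3.

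Genes that fell in both lines could include off-targets of a hairpin whose seed pairs with GCTTGCT. The z of −8.53, the lowest of all heptamers, fits this hypothesis. Sites followed by A, in 223 genes, had a mean of −0.15 ± 0.025 against genes with no site. Sites not followed by A, in 1132 genes, had −0.074 ± 0.011, and sites in coding sequence alone a smaller mean of −0.043. These values also fit, and the reverse complement had −0.007. The biological reading, a response to RUVBL1 loss itself, is not excluded. Of the 856 genes lower in both lines with a 3′ UTR, 165 (19.3%) held the site, against 94.4 expected at the share of genes called in neither line (11%), and the rest did not hold it. Of the 767 genes higher in both lines, 89 held it against 84.5 expected. The heptamer was picked from the same fold changes, so these counts are not an independent test. The same holds for the means of genes with a 3′ UTR site against genes with no site, also per line and per knockdown library. The expected counts are raw shares, not adjusted for 3′ UTR length, GC content or CPM. The hairpin sequence is not given in the sources used here, and no single gene was tested for a seed effect, so the choice stays open.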
